A study of Homo sapiens with 4 samples.

How the data were processed

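RNA from 4 modified colorectal cancer cell lines was measured on 1 array each, grouped by the sample titles as HCT116-Vec, HCT116-CDX1, LS174T-siVec and LS174T-siCDX1. Per the labels' protocols, total RNA was extracted with RNeasy and biotin-labelled cRNA was made from 2 µg of it with an Enzo kit. Per the submitters' processing notes, the authors processed the arrays with RMA, which subtracts background, equalises the distributions of arrays and summarises the probes of each probe set; its version and the set of arrays normalised together were not given in the sources used here. The deposited values were log2 expression of 54675 probe sets, ranging from 3.20 to 14.6, and were used as deposited. The labels did not state the constructs, and the meaning of Vec, siVec, CDX1 and siCDX1 was taken from the names.

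Probe sets were named from the platform annotation. Of the 54675, 41097 had 1 gene, 1801 several and 11777 none listed there, and a probe set with several genes named no gene. Symbols were updated through the gene identifier against RefSeq genes of assembly GRCh38.p14, where 41043 probe sets matched and 0 symbols changed. No genome build applies to the array values, so no coordinates are printed. Each of 19775 genes was read from its probe set with the highest mean over the 4 arrays, and 10523 genes had several probe sets.

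Within a comparison of 2 arrays a gene was measured where the brighter array was at least 6 on the log2 scale, and changed where the difference was at least 1, which is 2-fold. No p-value was computed for a comparison of 2 arrays. Fixed gene lists, 32 in all, with 753 distinct genes of which 688 were read, were described by their median difference and its percentile among 10000 random lists of the same size, drawn within 20 bins of mean expression, with at least 4 measured members. The lists included markers of cell types other than colorectal epithelium. For both pairs together, genes were counted in the 4 combinations of direction beside the number that independent lists give, the product of the 2 counts over the genes measured in both. All 4 arrays were also fitted with limma 3.58.1 in R 4.3.3, with the CDX1 label and the cell line as terms and 1 residual degree of freedom, for the 17280 genes whose brightest array was at least 6, with Benjamini-Hochberg adjusted p values. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

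The comparisons, rules, gene lists and alternatives were set before the data were examined. Named genes were CDX1 and KRT20, the 12 largest rises and 12 largest falls of each comparison of 2 arrays, up to 12 genes per direction that moved with CDX1 in both pairs, up to 5 in each opposed combination, and up to 4 members of each list with the largest change. Genes named beyond this, as the remaining members of a small count or as genes singled out, were chosen after their values were seen. The alternatives were no floor, a floor of 7, quantile normalization of the 4 arrays, equal medians, removal of a loess on the mean level (span 0.3), the mean of a gene's probe sets, leaving out probe sets marked as shared between transcripts (names ending in _x_at or _s_at), and thresholds of 1.5-fold and 3-fold. An alternative with levels under 6 set to 6, the measured genes kept, was added after the data were seen. The settings tried with limma also included no cell line term, an intensity trend and robust moderation.

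Array quality was compared through the correlation of probe sets and through control probe sets. Pearson r over probe sets was 0.988 within the HCT116 pair and 0.989 within the LS174T pair, and 0.933 to 0.937 between the lines. The difference of the 3' and 5' probe sets of GAPDH was -0.07, -0.03, -0.07 and -0.06 in HCT116-Vec, HCT116-CDX1, LS174T-siVec and LS174T-siCDX1. Each array had 16625 to 16716 genes at or above the floor. The 2-fold rule was tested on simulated data with the noise of the HCT116 pair over 19775 genes: it called 98% of 50 genes changed by 1.5 on the log2 scale, 2% of 50 changed by 0.5, and 0.0153% of unchanged genes. With 1 array per group the spread between replicate cultures could not be measured. These shares are therefore no error rate for the genes called changed. In 200 random lists of 25 genes from that pair 4.50% lay outside the central 95%, and 99% did above it after a shift of 0.3. The first share follows by construction for random lists. It gives no error rate for lists of genes that vary together, which were not simulated. The limma fit was tested on simulated data over 17280 genes and called 2% of 50 genes changed by 1, 88% at 2, 96% at 3 and 100% at 4, with 7 of 17080 unchanged genes called. Those 200 genes were changed together, which eases the adjusted p of each. With 1 changed gene per data set, in 50 data sets per size, the gene was called in 0% at 1 and at 2, 4% at 3 and 48% at 4.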

Results

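Gene expression was measured on 4 Affymetrix oligonucleotide arrays, with 1 array for each of 4 modified colorectal cancer cell lines. The lines formed 2 pairs. HCT116, a human colorectal carcinoma line, was measured as HCT116-Vec and HCT116-CDX1. LS174T, a mucin-producing human colon adenocarcinoma line, was measured as LS174T-siVec and LS174T-siCDX1. The names were read as a vector control and raised CDX1 in HCT116, and a vector control and lowered CDX1 in LS174T. CDX1 is a homeobox transcription factor of the intestinal epithelium, and the series asked whether it regulates cytokeratin 20, the product of KRT20. Values were RMA expression on the log2 scale, with array medians of 7.04 for HCT116-Vec, 7.06 for HCT116-CDX1, 7.04 for LS174T-siVec and 7.06 for LS174T-siCDX1. With 1 array per group, no difference within a pair has a replicate check, and the number of arrays limits the precision of every value below. A gene was taken as measured at a level of 6 or more in the brighter of 2 arrays, and "rose", "fell" and "changed" are used of measured genes that differed at least 2-fold between 2 arrays. Where the dimmer level lay under 6 it was no clear signal, and the fold printed is then the array reading; "at least" marks the fold against a level of 6, a bound chosen after the values were seen.

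KRT20 was higher where CDX1 was raised by label and lower where it was reduced. In HCT116 its level was 6.36 with the vector and 9.38 on the array labelled HCT116-CDX1, a rise of 3.03 on the log2 scale, or 8.14-fold. In LS174T it was 8.15 on the siVec array and 5.45 on the siCDX1 array, and it fell by 2.70, or 6.51-fold as read and at least 4.43-fold, since 5.45 lay under the level of a measured gene. CDX1 itself was read by 1 probe set, and so was KRT20. The CDX1 level was 10.46 in LS174T-siVec and 9.06 in LS174T-siCDX1, and it fell by 1.40. In HCT116 the CDX1 level was 8.21 with the vector and 8.24 on the array labelled HCT116-CDX1, a difference of 0.02. The probe set thus gave no sign of raised CDX1 in HCT116, every direction drawn for that pair rests on the label alone, and the array is called "the array labelled HCT116-CDX1" throughout. CDX2, the close relative of CDX1, was singled out after its values were seen: it stood at 7.52 and 7.62 in the HCT116 pair and at 9.49 and 9.14 in the LS174T pair.

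**Figure D1:**
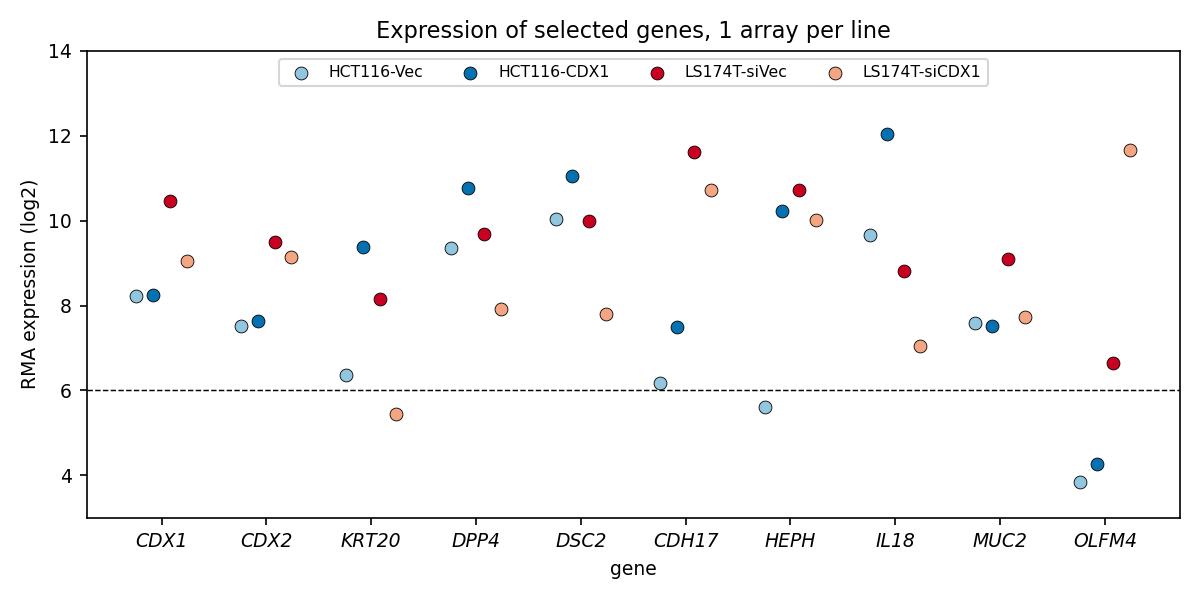
RMA expression (log2, vertical axis) of 10 genes (horizontal axis), with 1 point per array and the dashed line at the level of 6 that defined a measured gene. KRT20 stands at 6.36 and 9.38 in the HCT116 pair and at 8.15 and 5.45 in the LS174T pair, while CDX1 stands at 8.21 and 8.24 in the HCT116 pair and at 10.46 and 9.06 in the LS174T pair.

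The array labelled HCT116-CDX1 was set against HCT116-Vec to ask which genes change when CDX1 is introduced into HCT116. The largest rise was in HEPH, which encodes the intestinal copper ferroxidase hephaestin that acts in iron export, from 5.61 to 10.22 (24.4-fold as read, at least 18.7-fold). CCND2, a cyclin of the G1 phase, rose 16.5-fold as read and at least 6.66-fold, MMP1, an interstitial collagenase, from 4.68 to 8.67 (at least 6.39-fold), and CCL20, a chemokine of mucosal epithelium, 10.7-fold as read and at least 7.26-fold. Other large rises were those of CLMP at 3.31 on the log2 scale, SYTL2 at 3.12, LNCAROD at 2.97, SELENOP at 2.83, the keratin gene KRT23 at 2.72, ANTXR2 at 2.56 and the cytokine gene IL18 at 2.38. The largest falls as read were in CYP24A1, which encodes the vitamin D 24-hydroxylase and went from 8.91 to 4.59 (19.9-fold as read, at least 7.53-fold), and in NRIP1, a nuclear receptor corepressor, at -3.92; against a level of 6 NRIP1 was the largest, at -3.59. ADGRF1 followed at -3.32, VHRT at -2.62, PLA2G7 at -2.35, IKBIP at -2.28, MID1 at -2.17, LINC02458 at -2.12, ZNF512B at -2.11, EMP1 at -2.01, TRHDE at -1.95 and COL12A1 at -1.87. The dimmer level lay under 6 for 6 of the 12 rises and 6 of the 12 falls, so their order rests in part on readings of no clear signal.

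Of 16914 genes measured in the HCT116 pair, 155 rose and 164 fell. With a loess on the mean level removed the split was 178 to 126. The central 95% of gene differences ran from -0.78 to 0.65, and 18 spike-in probe sets differed by up to 0.349 in size, with a standard deviation of 0.125. Of 161 changed genes with several probe sets, 132 had the same sign in each of them and 74 had another probe set that changed alike. The second probe set of HEPH differed by -0.09, and 1 of the 4 probe sets of CCND2 by -0.11, so that the mean over probe sets was 2.26 for HEPH and 1.48 for CCND2.

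Genes of cell division were lower as a group on the array labelled HCT116-CDX1. Of 41 measured proliferation genes, 3 fell, 0 rose and 38 differed by less than 2-fold. The list median was -0.47, at percentile 0 of 10000 random lists of matched expression, and 37 members lay below 0. AURKA at -1.22, BUB1 at -1.16 and CDC20 at -1.12, a mitotic kinase, a checkpoint kinase and an activator of the anaphase-promoting complex, were the members that fell. AURKA differed by -0.27 without the probe sets marked as shared between transcripts, and BUB1 by -0.53 as the mean of its probe sets. The metallothioneins, small metal-binding proteins, had a median of -1.17, also at percentile 0. MT1E at -1.45, MT1F at -1.32, MT1H at -1.22 and MT1X at -1.17 fell, and the 3 other measured members lay below 0. These genes are close in sequence, so their probe sets are uncertain as separate readings.

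The list that joins the unfolded protein response with amino acid stress and the list of cholesterol and fatty acid synthesis lay above their random lists on the same array. Of 29 measured genes of the unfolded protein and amino acid stress list, 7 rose, 1 fell and 21 differed by less than 2-fold, with a median of 0.62 at percentile 100. CHAC1 rose by 2.12, the cystine transporter gene SLC7A11 by 2.06, the asparagine synthetase gene ASNS by 1.61 and DDIT4 by 1.32. SDF2L1, the member that fell, was at -1.23. Of 23 measured genes of cholesterol and fatty acid synthesis, 4 rose, 0 fell and 22 lay above 0, with a median of 0.48 at percentile 100. INSIG1 rose by 1.17, MSMO1 by 1.14, STARD4 by 1.10 and the squalene epoxidase gene SQLE by 1.03.

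Smaller shifts were seen in immune and signalling lists of the HCT116 pair. In the interleukin and NF-kappaB list 2 of 23 genes rose, CCL20 and IL18, and the median was 0.23 at percentile 100. In the antigen presentation list of 18 genes, HLA-DRA rose by 1.63 and PSMB10 fell by 1.22, with a median of 0.28 at percentile 100. In the list of RAS-MAPK output, SPRY4 rose by 1.46 and ETV5 from 10.08 to 11.08 among 21 genes, and the median was 0.26. ETV5 differed by -0.14 when read without shared probe sets and by 0.40 as the mean of its probe sets. The mucin and glycan synthesis list, which holds genes of glycan assembly and no mucin gene, with GCNT3 at 1.08 as the member of 26 that rose, had a median of 0.15. In the goblet cell list 0 of 29 genes changed, and in the immediate early list 0 of 20, with medians of 0.14 and 0.12. The hypoxia and glycolysis list had a median of 0.08 at percentile 97.54, with rises in ALDOC of 1.36 and VEGFA of 1.11. These last 4 lists fell back inside the central 95% of random lists under 2 to 5 of 7 other settings fixed beforehand.

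Intestinal differentiation genes moved in small numbers on the array labelled HCT116-CDX1. Of 36 measured genes of absorptive enterocytes, 3 rose and 33 differed by less than 2-fold: KRT20, the brush-border peptidase gene DPP4 at 1.41 and the liver-intestine cadherin gene CDH17 at 1.31. The list median was 0.08, at percentile 94.3. Of 19 measured genes described in the literature as CDX targets, 4 rose, HEPH, KRT20, CDH17 and the desmocollin gene DSC2 at 1.02, and the median was 0.10, at percentile 93.4. This list lay above its random lists with no floor, at 0.12, and with a floor of 7, at 0.22. Of 30 measured epithelial junction genes, 3 rose, the plakoglobin gene JUP at 1.36 with CDH17 and DSC2. The junction median was 0.07, at percentile 96.1, and it lay above its random lists with a floor of 7 and with the mean of probe sets. Of 13 measured keratin genes, KRT20 and KRT23 rose and the others differed by less than 2-fold, so that the list median, at -0.13, had the opposite sign to the 2 changes; it was 0.05 with no floor. KRT20 is the gene the series set out to examine, so its place in the absorptive, keratin and literature lists is not independent evidence. Among 26 HOX genes, with a median of 0.06 at percentile 81.7, 4 of the HOXB cluster rose: HOXB9 by 1.51, HOXB6 by 1.38, HOXB5 by 1.28 and HOXB8 by 1.02. HOXB8 was at 0.63 as the mean of its probe sets, and HOXB7, which lies between HOXB6 and HOXB8 and was singled out after its value was seen, differed by 0.31. Of 29 intestinal transcription factor genes, KLF5 rose by 2.05 and NR5A2 by 1.39, while EHF fell by 1.86, and the median was -0.02, at percentile 47.6. In the Wnt target list of 24 genes, BAMBI at -1.47, VSNL1 at -1.16 and NKD2 at -1.12 fell, 11 lay above 0 and 13 below, and the median was -0.01, at percentile 60.3.

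LS174T-siCDX1 was set against LS174T-siVec to ask which genes change when CDX1 is lowered in a line that expresses it. The largest falls as read were in IL33, which encodes an epithelial alarmin cytokine and went from 9.05 to 4.17 (29.6-fold as read, at least 8.31-fold), and in PIGR, the receptor that carries polymeric IgA across epithelium, from 12.35 to 7.66 (25.8-fold), the largest against a level of 6. Other falls were those of ARHGAP6 at -4.22, the mucin-like gene PARM1 at -4.14, RUBCNL at -4.02, CADPS at -3.91, PAQR5 at -3.51, MALL at -3.42, COL18A1 at -3.41, the adhesion molecule gene CEACAM6 at -3.29, COXFA4L3 at -3.24 and MTTP, needed for the assembly of apoB lipoproteins, at -3.18. The largest rises as read were in SPOCK3, from 3.74 to 9.02 (38.9-fold, at least 8.14-fold), and in OLFM4, a marker of intestinal crypt base cells, from 6.65 to 11.65 (32.2-fold); OLFM4 was the largest against a level of 6. BEX5 rose by 4.43, the homeobox gene SHOX2 by 4.13, ECI2 by 4.03, the cancer-testis antigen gene CTAG2 by 3.71, the galanin gene GAL by 3.55, the embryonic globin gene HBE1 by 3.49, DNAJC6 by 3.41, ADRA2A by 3.40, TM4SF4 by 3.12 and BNIP3 by 3.08. The dimmer level lay under 6 for 5 of the 12 rises and 4 of the 12 falls, so their order too rests in part on readings of no clear signal.

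Of 16896 genes measured in the LS174T pair, 101 rose and 211 fell. The central 95% of gene differences ran from -0.68 to 0.49, and the spike-in probe sets differed by up to 0.170 in size. Of 144 changed genes with several probe sets, 123 had the same sign in each of them and 87 had another probe set that changed alike. As means over probe sets the changes of SHOX2, GAL, HBE1 and DNAJC6 were smaller, at 2.34, 1.77, 1.77 and 1.80, and that of ARHGAP6 was -2.25.

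Literature CDX targets and the absorptive enterocyte, keratin and epithelial junction lists were lower in LS174T-siCDX1. Of 20 measured literature CDX targets, 8 fell, 0 rose and 12 differed by less than 2-fold, with a median of -0.80 at percentile 0 of matched random lists. Among those that fell were the tight junction gene CLDN2 at -2.89, KRT20 at -2.70, DSC2 at -2.19 and the drug efflux pump gene ABCB1 at -1.92. Of 37 measured absorptive enterocyte genes, 6 fell and 0 rose, with a median of -0.18 at percentile 0; these were CEACAM6, MTTP, KRT20, DPP4 at -1.76, the galectin gene LGALS4 at -1.64 and the guanylate cyclase C gene GUCY2C at -1.35. With levels under 6 set to 6, GUCY2C was at -0.74, and 5 absorptive and 7 literature genes were at least 2-fold lower. Of 14 measured keratin genes, 5 fell and 0 rose, with a median of -0.39 at percentile 0. Beside KRT20 these were KRT19 at -1.69, KRT13 at -1.51, KRT8 at -1.49 and KRT80 at -1.27; KRT19 was at -0.75 as the mean of its probe sets, and KRT13 at -0.94 with levels under 6 set to 6, which left 4 keratin genes at least 2-fold lower. Of 29 measured epithelial junction genes, 28 lay below 0 and 4 fell, CLDN2, DSC2, the P-cadherin gene CDH3 at -1.55 and CLDN1 at -1.41, with a median of -0.27 at percentile 0. KRT20 is a member of 3 of these 4 lists, again not as independent evidence, and CLDN2 and DSC2 stand in both the literature and the junction list. LGALS4 and GUCY2C, which fell, stand in both the literature and the absorptive list. Those lists share further members, among them CDH17 and VIL1, so they are not separate readings. Other intestinal lists lay inside their random lists with 0 genes changed: the medians were -0.03 for 28 intestinal transcription factor genes (percentile 48.1), 0.04 for 10 Paneth cell genes (64.0) and -0.02 for 13 enteroendocrine genes (23.6).

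The lists of mucin and glycan synthesis, RAS-MAPK output, immediate early genes, p53 targets and cholesterol synthesis also lay below their random lists in LS174T-siCDX1. In the mucin and glycan synthesis list 3 of 28 genes fell, FUT3 at -1.18, FUT2 at -1.13 and GCNT1 at -1.12, with a median of -0.38 at percentile 0. The goblet cell list moved in both directions, with TFF1 at -1.42, MUC2 at -1.37, MUC13 at -1.03 and SPINK4 at 1.31 among 31 genes, and its median of -0.06 lay at percentile 6.80. It lay below its random lists after quantile normalization, after the loess and with the mean of probe sets. In the list of RAS-MAPK output 5 of 21 genes fell and 0 rose, with a median of -0.42 at percentile 0. They included the phosphatase genes DUSP6 at -1.99 and DUSP5 at -1.21 and the chemokine gene CXCL8 at -1.32. In the immediate early list CCN2 at -2.25, EGR1 at -1.08 and IER3 at -1.07 fell among 19 genes, with a median of -0.23 at percentile 0.05. In the interleukin and NF-kappaB list 6 of 22 genes fell, among them IL32 at -2.04, IL18 at -1.77, CXCL1 at -1.57 and CXCL8, although the median was -0.02, at percentile 32.3. The p53 target list had a median of -0.20 at percentile 0.06, with CDKN1A at -1.22 as the member of 21 that fell. The cholesterol list had a median of -0.19 at percentile 0.29, with 0 of 23 genes changed. Without shared probe sets the immediate early, p53 and cholesterol lists lay inside the central 95% of random lists, and so did the cholesterol list with the mean of probe sets.

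The lists that were higher in LS174T-siCDX1 held few changed genes. The proliferation list had a median of 0.21 at percentile 100, with 35 of 41 genes above 0 and 0 changed. The HOX list had a median of 0.18 at percentile 99.9, with a rise in HOXB7 of 1.23 among 24 genes, and lay inside the range of random lists without shared probe sets. In the crypt stem cell list OLFM4 rose together with the aldehyde dehydrogenase gene ALDH1A1, by 1.15, and the median of 22 genes was -0.02, at percentile 61.6.

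In each pair 11 of 32 lists lay outside the central 95% of random lists. They were 9 above and 2 below for HCT116, and 2 above and 9 below for LS174T. The lists share genes and hold genes that can vary together, so the number that no effect would give is not known. Without shared probe sets 31 lists had enough members, the metallothioneins having too few; 6 of them lay outside in HCT116 and 7 in LS174T. With a floor of 7 the counts were 15 and 13, and after quantile normalization or the loess they were 10 and 13. Markers of cell types foreign to these cultures lay inside in both pairs. The fibroblast marker medians were 0.11 for HCT116 and -0.05 for LS174T, the leukocyte marker medians were 0.07 and 0.09, and the endothelial marker medians were 0.01 and 0.04. Reference genes with housekeeping roles had medians of -0.08 and -0.08, and the HCT116 median was 0.01 after the loess.

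**Figure D2:**
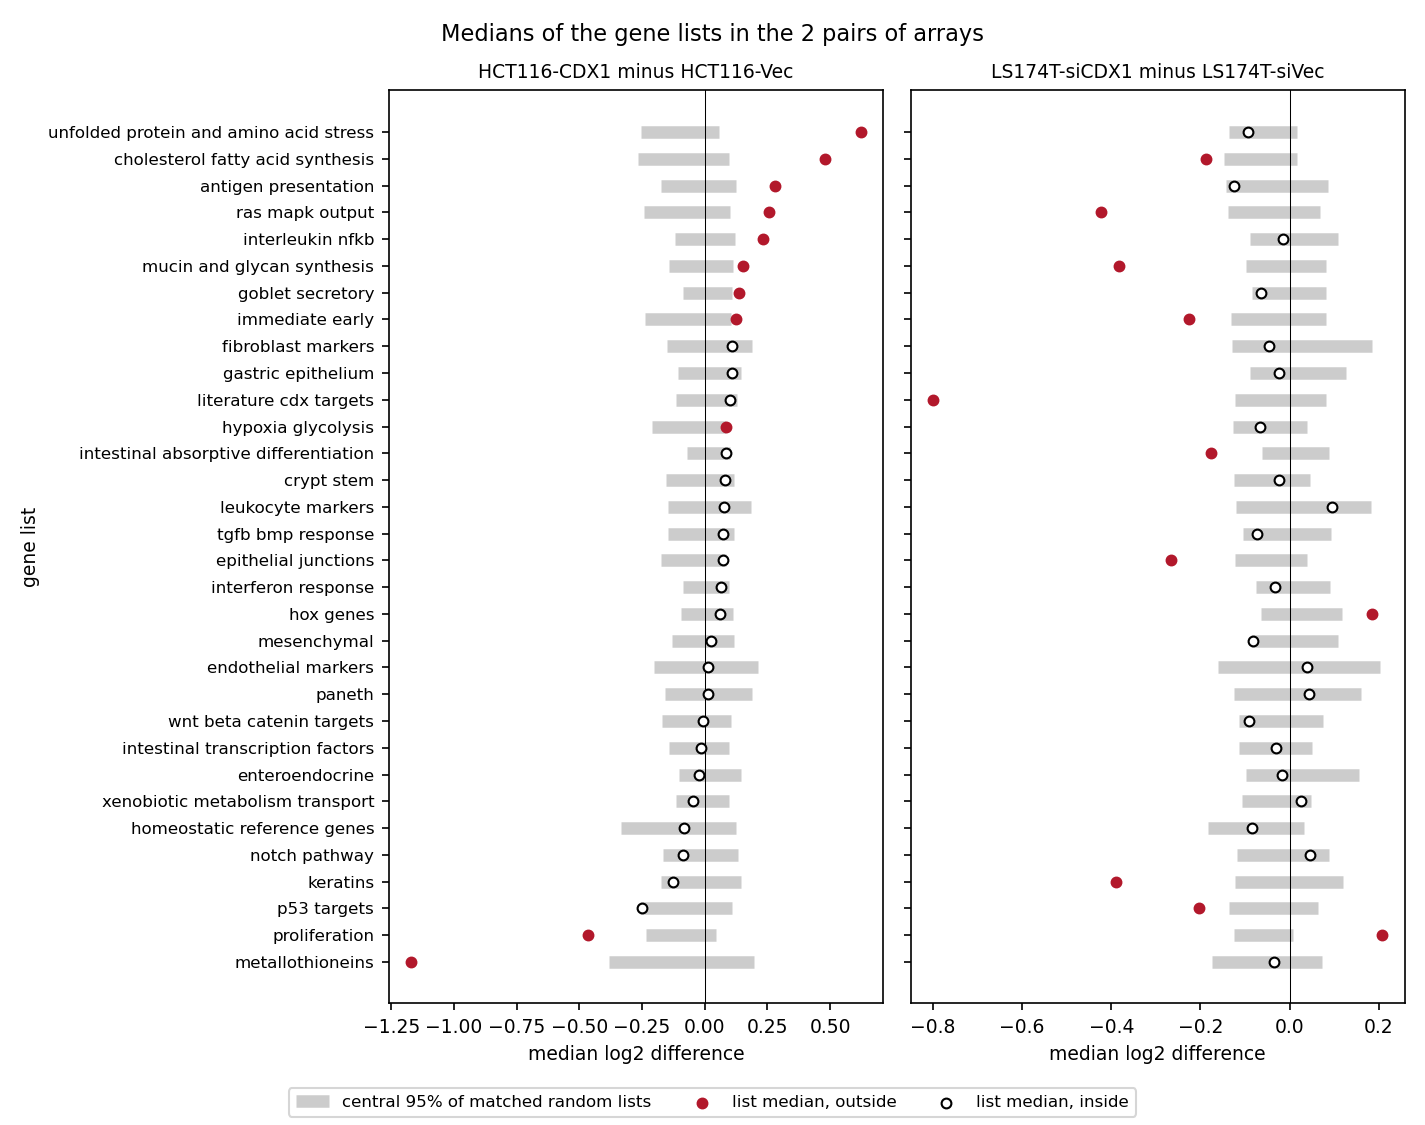
Median log2 difference (horizontal axis) of 32 gene lists (vertical axis) in the HCT116 pair on the left and the LS174T pair on the right, 1 array per line. Grey bars are the central 95% of 10000 random lists of matched expression, filled points lie outside them and open points inside; the proliferation list is at -0.47 on the left and 0.21 on the right, and the literature CDX targets are at 0.10 and -0.80.

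The pairs were then compared to find genes that moved with CDX1 by label in both lines. Among 16530 genes measured in both pairs, 18 rose on the array labelled HCT116-CDX1 and fell in LS174T-siCDX1, where independent lists of this size share 1.53. Of the 7713 genes that differed with CDX1 in sign, KRT20 ranked 1 by the smaller of its 2 changes, at 2.70, ahead of IL18 at 1.77; with levels under 6 set to 6 it ranked 1 at 2.15. Next by that measure were the chloride channel gene CLIC3, at 1.63 and -1.68, EPS8L3, an epithelial actin regulator gene, at 1.51 and -1.66, the mesothelin gene MSLN at 1.49 and -1.89, DPP4 at 1.41 and -1.76, and CCL20 at 3.41 and -1.31. GASK1B, PDE9A, CEMIP, the laminin gene LAMB3 and PRSS23 completed the 12 largest, with smaller changes of 1.24 down to 1.13. FGFBP1, PARM1, H2AC6, ANTXR2, DSC2 and PAPSS2 were the other members. PDE9A and PRSS23 were below 2-fold in HCT116 as means over probe sets, at 0.58 and 0.64, and so was CEMIP at 0.84. GASK1B was at 0.80 in HCT116 with levels under 6 set to 6.

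The reverse combination, a fall on the array labelled HCT116-CDX1 and a rise in LS174T-siCDX1, held 2 genes against 0.725 for independent lists. They were ECI2, a peroxisomal enoyl-CoA isomerase gene, at -1.07 and 4.03, and the cytochrome P450 gene CYP1B1 at -1.06 and 1.05. The count was 0 without shared probe sets and 1 under 5 other settings; CYP1B1 was at -0.52 in HCT116 with levels under 6 set to 6. Changes against the CDX1 labels were fewer: 5 genes rose in both modified lines and 4 fell in both, against 0.674 and 1.65 for independent lists. Across the 16530 genes, which are not independent replicates, the differences of the 2 pairs had a Pearson r of -0.00653 and a Spearman rho of 0.0647. Among the 521 of them that changed in either pair these were -0.0896 and -0.114. A negative value is the direction with CDX1 by label. Among the 193 genes that fell in LS174T-siCDX1 and were measured in HCT116, 59.1% were higher on the array labelled HCT116-CDX1, with a median of 0.09. Among the 131 genes that rose on that array and were measured in LS174T, 35.9% were higher in LS174T-siCDX1, with a median of -0.18. The reverse sets did not lean with CDX1: of 85 genes that rose in LS174T-siCDX1, 55.3% were higher on the array labelled HCT116-CDX1, with a median of 0.03, and of 141 genes that fell on that array, 40.4% were higher in LS174T-siCDX1, with a median of -0.07. In each pair the sets of both directions thus leaned the same way. For that reason these shares alone do not mark a lean with CDX1. Over all 16530 genes a minority, 7713, differed with CDX1 in sign.

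**Figure D3:**
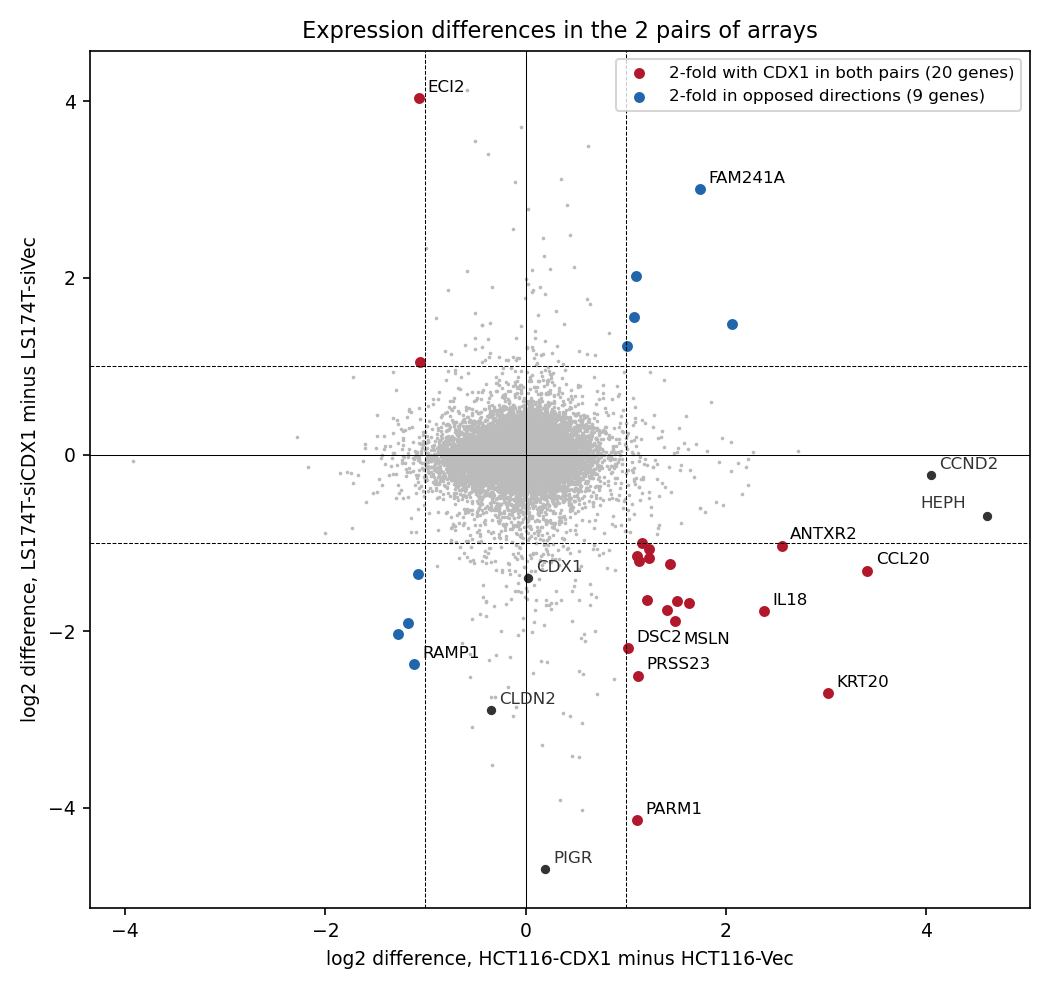
Log2 difference of each of 16530 genes in the HCT116 pair (horizontal axis) and in the LS174T pair (vertical axis), 1 array per line, with dashed lines at 2-fold. Red points are the 20 genes that changed with the CDX1 label in both pairs and blue points the 9 that changed against it; KRT20 lies at 3.03 and -2.70.

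The arrays of higher and lower CDX1 by label were also compared in 1 limma fit with the cell line as a block, which treats the pairs as 2 replicates of 1 effect. KRT20 ranked 1 of 17280 genes, with a mean difference of 2.86 (SE 0.16) and an adjusted p of 0.502 from limma, and it moved with the label in 2 of 2 pairs. It ranked 5, with an SE of 0.59, without the cell line term. The mean difference uses its LS174T-siCDX1 level of 5.45 as read, which lay under 6. No gene passed an adjusted p of 0.05 (0 genes called). An unadjusted limma p under 0.05 was found for 518 genes. That is fewer than the share of 0.05 of the 17280 genes that no effect would give. In data simulated for this fit with 1 changed gene, that gene was called in 0% of 50 data sets at a change of 2 on the log2 scale, 4% at 3 and 48% at 4. Adjusted over the list alone, 3 of 39 absorptive enterocyte genes were called by limma, KRT20 at an adjusted p of 0.00113, DPP4 at 0.00810 and CDH17 at 0.0284, and 0 were called over all genes. Of 20 literature CDX targets, KRT20, CDH17 and DSC2 were called when adjusted over the list alone, with adjusted p values from limma of 0.000582, 0.0219 and 0.0345. KRT20 among 14 keratin genes, IL18 among 23 interleukin and NF-kappaB genes and CYP1B1 among 33 xenobiotic metabolism genes were the calls in other lists, with limma adjusted p values over the list alone of 0.000407, 0.00704 and 0.0418. Every list was adjusted on its own, so the list-alone values make no allowance for the number of lists. KRT20 is the gene of the series, so its calls in several lists are not independent evidence. The CYP1B1 level on the array labelled HCT116-CDX1 was 5.46, under 6. With levels under 6 set to 6 its HCT116 difference was -0.52. The limma p values rest on the spread between 2 lines, with 1 residual degree of freedom, moderated by a prior of 3.45 degrees of freedom pooled over genes. They hold no spread between replicates within a line and assume that raising and lowering CDX1 move a gene alike.

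LS174T-siVec was set against HCT116-Vec to describe the background in which CDX1 was altered; cell line and kind of vector differ together in this comparison. The goblet cell genes AGR2 and AGR3 and the enterocyte gene LGALS4 were among those with the largest differences. AGR2 was 154-fold higher and LGALS4 136-fold. CCND2 was 226-fold higher as read and at least 91.0-fold, ALDH1A1 84.5-fold and at least 55.5-fold, the lysozyme gene LYZ 77.9-fold and at least 38.1-fold, and AGR3 89.0-fold and at least 33.3-fold. TMEM132D-AS1, NRN1, LINC01088, LRATD1, ZNF595 and FSTL5 made up the other large differences in that direction, from 6.94 to 6.08 on the log2 scale. HCT116-Vec had the higher level of MARCKS, at -7.25, PHLDB2 at -7.06, GNAI1 at -6.66, the retinal dehydrogenase gene ALDH1A3 at -6.60, the caveolin gene CAV2 at -6.34, the cancer-testis gene MAGEB2 at -6.33, the carbonic anhydrase gene CA2 at -6.21 and the phosphodiesterase gene PDE4B at -6.21. TMEM200A, NPW, TOX2 and TCEAL9 were at -6.44 to -6.26. Against a level of 6 the largest were AGR2 in the first direction and ALDH1A3, at 97.3-fold, in the second. The dimmer level lay under 6 for 8 of the 12 genes named as higher in LS174T-siVec and 11 of the 12 named as higher in HCT116-Vec. Of 17043 genes, 1028 were at least 2-fold higher in LS174T-siVec and 1250 at least 2-fold lower.

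Literature CDX targets were higher in LS174T-siVec. Of 20 measured literature CDX targets, 11 were at least 2-fold higher and 0 lower, with a median of 1.47 at percentile 100, and they included LGALS4, CDH17 at 5.44, HEPH at 5.11 and ABCB1 at 4.85. The medians of the absorptive enterocyte, epithelial junction and keratin lists, at 0.11, 0.13 and 0.07, lay inside their random lists, at percentiles of 94.98, 92.6 and 77.3; the absorptive list lay above with a floor of 7 and the junction list with the mean of probe sets. Of their members, 10 of 39 absorptive genes were higher and 1 lower, 6 of 30 junction genes higher and 3 lower, and 3 of 14 keratin genes higher and 1 lower. The intestinal transcription factor list, with 11 of 29 higher and 2 lower, had a median of 0.77 at percentile 100, with GATA6 at 2.26 and FOXA1 at 2.22. The crypt stem cell list, with 10 of 23 higher and 2 lower, had a median of 0.70 at percentile 100, with ASCL2 at 4.90 and EPHB3 at 4.34. Lists of goblet cells, cholesterol synthesis, mucin and glycan synthesis, xenobiotic metabolism and metallothioneins also lay above their random lists, at medians of 0.31, 0.89, 0.53, 0.44 and 0.84. HOX genes, with 8 of 26 lower and 0 higher, had a median of -0.47 at percentile 0.01, and the mesenchymal list, with 10 of 24 lower and 2 higher, a median of -0.40 at percentile 0, which lay inside its random lists without shared probe sets. In all, 17 of 32 lists lay outside, 11 above and 6 below, and without shared probe sets 12 of 31. With levels under 6 set to 6 the 2-fold counts were 1 smaller for the literature, absorptive, keratin, crypt stem cell and HOX lists, and 8 mesenchymal genes were lower. KRT20 was 1.79 higher in LS174T-siVec, and CDX1, at 10.46 against 8.21, was higher as well.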

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

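The tests weighed in this part were chosen after the result was seen, except the one with a floor of 7. Genes stood out here because they changed at least 2-fold in the same direction in both modified lines, so that their change with CDX1 by label was opposite in HCT116 and LS174T. With 1 array per group the difference between the 2 effects was not tested.

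The CDX1 effect in HCT116 minus the CDX1 effect in LS174T, on the log2 scale, was 4.75 for FAM241A, 3.54 for MATN2, 3.13 for NAP1L5, 2.65 for LONRF1 and 2.24 for BDH2, which rose in both modified lines. FAM241A rose 3.35-fold in HCT116 and 8.02-fold in LS174T, and MATN2, an extracellular matrix protein gene, by 2.06 and 1.48 on the log2 scale. The same difference was -3.48 for RAMP1, -3.30 for S100A10, -3.08 for CLU and -2.42 for CAP2, which fell in both. CLU, the clusterin gene, was at -1.17 and -1.91, and S100A10 at -1.27 and -2.03. As means over their probe sets, MATN2, LONRF1, CLU and S100A10 were below 2-fold in both pairs, and BDH2 and CAP2 in HCT116.

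More genes changed with the CDX1 label in both pairs than independent lists give, 20 genes in both directions, and 9 changed against it. Noise in dim probe sets stays open. With a floor of 7 the count with CDX1 in both directions, 18, was 8.65 times the 2.08 that independent lists give. That floor applied to the brighter array, which a dim gene can bring to 7 through the 2-fold change itself. The count therefore cannot tell such noise from a response. Genes that vary between any 2 arrays of cultured cells, whatever was altered, could also raise the overlap, in every combination alike. Of the 29 genes changed in both pairs, 69.0% moved with CDX1 (exact 95% interval 49.2 to 84.7%), where independent lists give 49.3%, which leaves this explanation open. A response to CDX1 shared by both lines remains open as well, as an untested hypothesis.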

How the results depend on the processing

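The alternatives were planned, except that with levels under 6 set to 6, which was chosen after the data were seen. KRT20 changed at least 2-fold with CDX1 in both pairs under every alternative. Limma called 0 genes under any of its 7 alternatives, with 47 to 654 genes at an unadjusted p under 0.05. In each of them that was fewer than a share of 0.05 of the genes tested. The limma adjusted p for KRT20 ran from 0.0797 with an intensity trend to 0.9999 without the cell line term. At 1.5-fold and at 3-fold the counts of higher genes were 570 and 43 in HCT116, 291 and 44 in LS174T and 2084 and 487 between the vector arrays, and those of lower genes 1033 and 26, 547 and 85, and 2433 and 627. For both pairs the counts at these thresholds were 65 and 3 up in HCT116 and down in LS174T, 24 and 0 in the reverse combination, 26 and 1 up in both modified lines, and 41 and 0 down in both. The reverse combination counted 1 with a floor of 7, quantile normalization, loess, the mean of probe sets or levels under 6 set to 6, and 0 without shared probe sets. Genes up in both counted 2 with the mean of probe sets, 3 without shared probe sets, 6 after the loess and 7 after quantile normalization. Genes down in both counted 1 with the mean of probe sets and 5 without shared probe sets. The combination up in HCT116 and down in LS174T, 18 as deposited, counted 13 without shared probe sets. It counted 14 with the mean of probe sets and 16 after quantile normalization. Without shared probe sets 6 lists in HCT116 and 7 in LS174T lay outside their random lists, of 31 evaluated, as the metallothioneins had too few members; in HCT116 the goblet cell, hypoxia, immediate early and mucin lists lay inside, and in LS174T the HOX, p53, cholesterol and immediate early lists. Across all alternatives the number of lists outside ran from 6 to 15 in HCT116, 7 to 13 in LS174T and 12 to 18 between the vector arrays. With a floor of 7 the lists gained in HCT116 were epithelial junctions, literature CDX targets, interferon response, p53 targets and TGF-beta and BMP response, and in LS174T gastric epithelium and antigen presentation. Quantile normalization and the loess each added the goblet cell and mesenchymal lists in LS174T. ETV5, read without shared probe sets, turned to -0.14 in HCT116 and MT1G likewise to -0.0325 between the vector arrays. The thresholds move counts by construction, and fewer genes are read without shared probe sets; for the other shifts the cause was not tested. The share of higher genes in HCT116 was 48.6% as deposited, 54.8% after quantile normalization and 58.6% after loess. Of 90 named changes in HCT116, 23 were below 2-fold under at least 1 alternative, 19 of them with the mean of probe sets. For LS174T these were 14 of 85 and 12, and between the vector arrays 16 of 113 and 7. Without shared probe sets only 63, 61 and 90 of these named changes could be read, so the others were not tried there. Leaving out 1 array leaves the limma fit no residual degree of freedom and gives no value. Genes whose signal over background stayed under the floor on both arrays of a comparison were left out, except in the alternative with no floor.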

Other observations

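The tests of the CDX1 probe set, the draws matched on level, and the counts of histone genes and neighbours were chosen after the result was seen; the tests for RNA of the other line were not. Of 14 histone H2B genes read, 7 were measured in both pairs. Of these, 6 were higher on the array labelled HCT116-CDX1 and lower in LS174T-siCDX1, with medians of 0.86 and -0.61 over the 7; none reached 2-fold in HCT116 and 1, H2BC12, did in LS174T. H2BC13 was at 0.18 and 0.12. H2BC12 was at 0.78 and -1.11, and H2BC5 at 0.97 and -0.61. Their probe sets were marked as shared between transcripts in 5 of 7, so they are not separate readings, and H2AC6, a histone H2A gene, changed 2-fold in both pairs.

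A minority of changed genes lay next to each other in gene order. In HCT116, 30 of 319 changed genes (9.40%) stood beside a gene changed in the same direction, against a mean of 5.86 (central 95% 0 to 14) in 1000 shuffles of the calls. In LS174T they were 20 of 311 (6.43%), against 6.32 (0 to 14). The HCT116 neighbours included KRT20 with KRT23, HOXB5 with HOXB6, HOXB8 with HOXB9, and metallothionein genes. The LS174T neighbours included CXCL8 with CXCL1, S100A10 with S100A11 at -2.03 and -1.24, and HBE1 with the olfactory receptor gene OR51B4 at 3.49 and 2.83. The count of neighbours was first run as a test of a regional copy number difference and then dropped as one after its result was seen, because it covers all changed genes and not the largest rises; it is given as a value. A stretch of 40 measured genes from HEBP2 to RAET1E had a median of -0.32 in HCT116, with 28 genes below 0, where the lowest stretch in 200 shuffles was at -0.30, and the highest, from CCNI to AFF1, was at 0.26, against 0.25. The lowest and highest stretches of LS174T, at -0.18 and 0.18, lay inside their shuffles.

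The CDX1 probe set did not differ between the HCT116 arrays, at 0.02. An exchange of the 2 HCT116 labels stays open. Of 22 genes that fell in LS174T-siCDX1 and changed in HCT116, 18, or 81.8% (exact 95% interval 59.7 to 94.8%), were higher on the array labelled HCT116-CDX1, but this bears on the labels only if CDX1 acts alike in both lines, which these values leave open. This interval too treats genes of the same arrays as independent draws, which they are not. A probe set that cannot read CDX1 RNA was argued against by its difference of -1.40 in LS174T. The introduced transcript may lack the part that the probe set reads, but the array holds 1 CDX1 probe set and no second reading, so this cannot be told apart from a line with no more CDX1 RNA than its control.

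Genes far higher in the other line stood among the largest rises of each pair. At least 4-fold higher in the other vector array were 2 of the 12 largest rises in HCT116, HEPH and CCND2, and 6 of 12 in LS174T: SHOX2, ECI2, GAL, HBE1, DNAJC6 and BNIP3. RNA of the other line was argued against, since the 100 genes most above in that line differed by a median of 0.16 in HCT116 and 0.13 in LS174T, where the shares needed by these rises give 3.12 and 4.39; AGR2 at 0.44 in HCT116 and MAGEB2 at 0.10 in LS174T were examples, while MARCKS, at 1.94 in LS174T, was not. Draws of 12 genes matched on their level in the vector array held 0 to 2 such genes in the central 95%. A low starting level could thus account for the 2 of HCT116. The 6 of LS174T lay above the highest of 10000 draws, 5, so the level alone did not give them. However, the rise and the comparison with the other line both used the same vector array, and the drawn genes were not chosen for rising. These draws therefore cannot exclude readings that were too low on LS174T-siVec alone. A response to lowered CDX1 in LS174T stays open. Genes that vary between any 2 arrays stay open too, since the draws matched only the level. Neither was tested.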
